A study of Mus musculus with 8 samples.

How the data were processed

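RNA from 4 primary cultures of mouse hind limb muscle was measured on 2 Affymetrix array types, MOE430A and MOE430B, which carry 22690 and 22575 probe sets. Each culture was hybridised to both types, which gives 8 arrays. Per the labels, the MACS cultures (replicates 2 and 3) were purified with magnetic beads for Sca1 and against CD45. The PP6 cultures (replicates 2 and 3) were purified by preplating, in which cells are separated by how fast they attach to a dish. Per the labels, cells grew in F10 Ham medium with serum, RNA was taken with a column kit and was not amplified, and contaminating cells were muscle cells in both preparations. The labels give the number of cells and the RNA concentration of each culture, and a purity estimate for MACS only.

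The deposited value tables hold signal intensity on a linear scale, 1 value per probe set and array. Per the submitters' processing notes the signals come from MAS5, whose version is not given in the sources used here. The 2% trimmed mean of every deposited MOE430A array was 1501 and that of the MOE430B arrays 1500, so the arrays had been scaled to a common level before deposit. The deposited tables used here carry no detection calls, so no rule for signals above background could be applied, and a fold against a dim signal has no stated bound. Scanner setting files deposited with each array hold settings rather than measurements. They were used only to count chip lots, days, stations and fluidics modules: per array type, the 4 arrays shared 1 lot, 1 hybridisation day, 1 scan day and 1 station, and each culture had its own module, so 4 modules served 4 cultures.

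Probe sets were named through the annotation tables supplied with the arrays, with symbols updated through Entrez gene identifiers to the NCBI RefSeq annotation of the mouse assembly. On MOE430A, 20393 probe sets carried 1 gene symbol, 691 several and 1606 none. On MOE430B the numbers were 14674, 245 and 7656. An updated symbol was found for 20364 and 14499 of those with 1 symbol. No gene was named from a probe set with several symbols, and genes of a list with no such probe set, Ly6a among them, were not analysed here. No genome coordinates were used.

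Signals were scaled to the mean trimmed mean of each array type, which changed the values very little, and log2-transformed with no pseudocount. The 2 array types were stacked. The 100 probe sets present on both types kept their MOE430A value, and the 64 control probe sets of each type were left out. A probe set was tested when its signal lay above the median of its own array in at least 2 of the 4 cultures, which left 23963 of 45037 probe sets. PP6 was compared with MACS in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, on 2 cultures per group, with 2 residual degrees of freedom per probe set and 5.67 after moderation. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. For each of 12278 genes 1 probe set was used: among those that passed the filter, MOE430A before MOE430B, then the highest mean signal.

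There were 20 gene lists. Of these, 18 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the 18 lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves on balance to 1 side, were run beside it. With an estimated correlation camera tests on the 2 residual degrees of freedom, as fry does. A list that misses there may do so for lack of cultures, for correlated members or for both. Counts of members past the threshold are given over all tested probe sets and adjusted over the list alone. The genes named were chosen by a rule. It took the 12 largest rises and falls past the threshold. As no gene passed, it took the 10 genes with the smallest p in each direction, without clone-like symbols. It added up to 4 members with the smallest p of each list, and Ly6a, Ptprc, Cd34, Pax7, Myod1, Myog, Des, Pdgfra and Kit where measured. Other members are named where a count or a group is described, and were then chosen after their values were seen. The groups, tests, lists, rule and most alternatives were fixed before the data were examined.

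The alternatives were the values as deposited, quantile normalization, centring on the median, a pseudocount at the 20th percentile of signal (128.0 and 200.9), no filter, a filter at the 75th percentile, eBayes without the trend, and each array type fitted alone. Others left out probe sets with the suffixes _x_at and _s_at, used the replicate number as a block, left out each culture in turn, averaged all probe sets of a gene, or let camera estimate the correlation. A floor at the array median, which raised all dimmer signals to it, was added after seeing the data. With each array type alone, lists were tested on the genes of MOE430A only.

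The procedure was tested on simulated data with the means and spread of the 23963 tested probe sets, 2 cultures against 2, in 20 runs with 23763 unchanged probe sets each. Of changes of 1 log2 unit, 0.2% passed the threshold. The share was 12% for 2 units, 51.2% for 4 units and 60.6% for 6 units, and 96 unchanged probe sets passed over all 20 runs. A list of 20 genes shifted by 1 log2 unit was recovered by camera in 20 of 20 runs, and 0 of 340 unshifted lists passed. These simulated genes were independent of each other. The number of arrays limits the precision of all values. The labels number the cultures of a group without saying whether they came from separate animals, so p-values measure the spread between these cultures, which may be partly technical.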

Results

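Gene expression was measured in putative stem cells from mouse hind limb muscle, prepared in 2 ways. The MACS cultures were sorted with beads for Sca1, a surface marker of many muscle-resident progenitors, and against CD45, the common leukocyte antigen. Their purity by flow cytometry was given as over 80% Sca1-positive and under 1% CD45-positive cells. The PP6 cultures were obtained by preplating, and no purity was estimated for them. Each group had 2 cultures, numbered 2 and 3. RNA concentration was 55 and 65 ng/ul for MACS and 35 and 15 ng/ul for PP6. Across the tested probe sets, log2 signals of the MACS cultures correlated with each other at r = 0.858 and those of the PP6 cultures at r = 0.839. Pairs from different groups correlated at 0.783 to 0.835. These are correlations across probe sets, which are not independent replicates. The comparison of PP6 with MACS asks how the transcripts of cells purified by preplating differ from those of cells sorted for Sca1.

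At the preset correlation of camera, the haematopoietic and macrophage, muscle differentiation and matrix lists were higher in PP6, and the cell cycle and endothelial lists were lower. With an estimated correlation none of these 5 lists passed, at adjusted p of 0.411 to 0.419, and no cell cycle or endothelial member passed when adjusted over its list alone. That camera test has 2 degrees of freedom, so a miss does not show that correlated members made the call. The 10 genes with the smallest p among those higher in PP6 were Lpl, Ngp, Saa3, S100a8, Cxcl12, Chil3, S100a9, Lgals3, Mpo and Prtn3. Of these, Ngp, S100a8, S100a9, Mpo and Prtn3 encode abundant proteins of neutrophil granules or cytosol. Log2 signal of S100a8 was 9.64 ± 0.07 in MACS and 15.56 ± 1.40 in PP6 (SD, n = 2), a 60.3-fold difference. Its log2 difference was 4.92 without PP6 replicate 3 and 6.91 without PP6 replicate 2. Ngp stood at 10.23 ± 0.69 and 16.17 ± 1.06, a 61.4-fold difference, or 5.19 log2 units without PP6 replicate 3 and 6.69 without PP6 replicate 2. Lpl, the lipase that releases fatty acids from lipoproteins, went from 13.03 ± 0.08 to 15.36 ± 0.21, a 5.01-fold difference. The acute-phase gene Saa3 differed by 4.35 ± 0.44 log2 units (SE), the chemokine gene Cxcl12 by 1.96 ± 0.21 and the galectin gene Lgals3 by 2.07 ± 0.23. A second tested probe set of Cxcl12 gave -0.46. Chil3 and Prtn3 were far below the array median in MACS, so their differences of 9.27 ± 0.99 and 6.39 ± 0.75 depend on dim signals. With signals below the array median raised to it, an alternative chosen after seeing the data, they were 5.44 and 3.39.

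The 10 genes with the smallest p among those lower in PP6 were Edn1, Ccn1, Dusp5, Shq1, Cxcl1, Vgll3, Med14, Srsf2, Bdkrb2 and Aplnr. Edn1, which encodes the vasoconstrictor endothelin 1, had a log2 signal of 13.37 ± 0.23 in MACS and 11.32 ± 0.22 in PP6 (SD, n = 2). Ccn1, a matricellular protein gene, differed by -1.95 ± 0.25 log2 units (SE), with all 4 tested probe sets between -2.29 and -0.99. The neutrophil-attracting chemokine Cxcl1 differed by -1.74 ± 0.24 and the apelin receptor gene Aplnr by -2.28 ± 0.36. The ERK phosphatase gene Dusp5 differed by -2.82 ± 0.37, Shq1 by -2.77 ± 0.37 and the bradykinin receptor gene Bdkrb2 by -3.74 ± 0.58. These 3 were dim in PP6, and with the floor at the array median they differed by -1.60, -1.44 and -1.13. The differences of Vgll3, Med14 and Srsf2 lay between -1.60 and -1.43, and further probe sets gave 0.21 for Srsf2, -0.13 for Med14 and -0.55 for Aplnr. With no filter another, dimmer probe set stood for Bdkrb2, with 0.39, and for Med14, with 1.41.

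With limma no probe set passed an adjusted p of 0.05 in either direction, 0 higher and 0 lower of 23963, and the smallest adjusted p was 0.255. At an unadjusted p under 0.05 there were 1364 probe sets higher and 1396 lower, where 1198 in all are expected by chance. Counted by gene, 713 were higher and 668 lower of 12278. Without the intensity trend 0 passed as well, with 1303 higher and 1093 lower at an unadjusted p under 0.05. Fitted alone, MOE430A gave 55 probe sets higher and 16 lower past the threshold, among them the 10 genes named as higher and Edn1, Ccn1, Cxcl1 and Aplnr, and MOE430B gave 0. A filter at the 75th percentile of signal left 5 probe sets past the threshold, those of Ngp, Saa3, S100a8, S100a9 and Lpl, each at an adjusted p of 0.0422. Centring the arrays on their medians moved the median difference of all probe sets by -0.12 log2 units and gave 948 higher and 1983 lower at an unadjusted p under 0.05. At that p there were 648 probe sets and 348 genes higher without PP6 replicate 3, 863 and 454 higher without PP6 replicate 2, and 918 probe sets lower without MACS replicate 2. Genes lower numbered 444 without PP6 replicate 3. S100a8 passed the threshold without PP6 replicate 2, at an adjusted p of 0.045. An exact permutation test of 2 cultures against 2 cannot give a two-sided p below 33.3%.

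**Figure D1:**
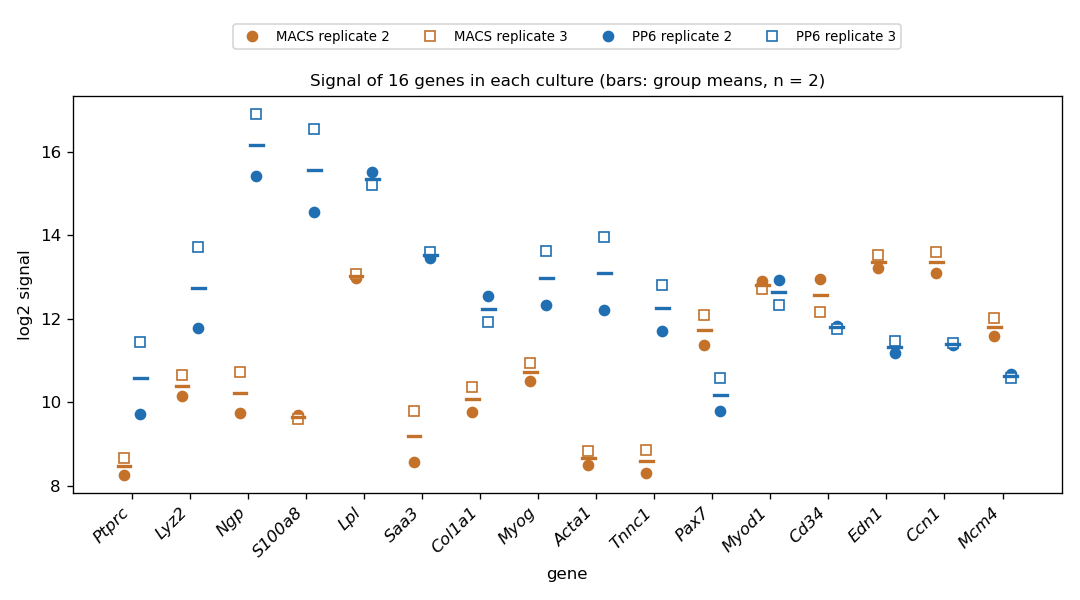
Log2 signal (vertical axis) of 16 genes (horizontal axis) in each of the 4 cultures, with circles for replicate 2, squares for replicate 3 and bars for the group means (n = 2). The S100a8 means were 9.64 in MACS and 15.56 in PP6, while the Myod1 values of the groups overlap.

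Leukocyte genes were higher in PP6. All 15 tested members of the haematopoietic and macrophage list had a positive difference, with a median of 2.11 log2 units, or 1.63 with no filter. A gene below the array median in both MACS cultures was tested only if above it in both PP6 cultures. The filter thus fixed the sign of such genes, and the count of positive members is partly built in. The list passed camera at an adjusted p of 4.18e-10. The adjusted p was 0.411 with an estimated correlation, which was 0.704 for this list. Adjusted over the list alone 8 of 15 members rose, and over all genes 0. Ptprc, which encodes CD45, the antigen selected against in the MACS sort, had a log2 signal of 8.46 ± 0.29 in MACS and 10.57 ± 1.22 in PP6 (SD, n = 2). Cd53 rose by 2.16 ± 0.55 (SE), the lysozyme gene Lyz2 by 2.35 ± 0.64, the adaptor gene Tyrobp by 2.66 ± 0.71 and Laptm5 by 1.42 ± 0.37, each adjusted over the list alone. Without PP6 replicate 3 the differences were 1.25 for Ptprc, 1.37 for Lyz2 and 1.57 for Tyrobp. With the floor at the array median the difference was 1.41 for Ptprc, and another probe set stood for Laptm5, with 2.60. Probe sets of Laptm5 ranged from 1.06 to 3.03. The list stood 1.25 above the MACS mean in PP6 replicate 2 and 2.97 above it in PP6 replicate 3, as medians, so its median without PP6 replicate 3 was 1.25. With the floor at the array median, it was 1.40, since 8 of the 15 members had MACS means below the array median.

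Genes of muscle differentiation and the sarcomere were higher in PP6 by a median of 3.03 log2 units. The list passed camera at an adjusted p of 1.2e-18, and the adjusted p was 0.411 with an estimated correlation. Adjusted over the list alone 22 of 25 tested members rose and 0 fell, and over all genes 0 passed. Fitted alone, MOE430A put 5 members past the threshold: Tnni1, Acta1, Tnnc1, Tnnt1 and Atp2a1. The troponin gene Tnnc1 rose by 3.67 ± 0.46 (SE), skeletal actin Acta1 by 4.42 ± 0.59, Tnnt1 by 3.16 ± 0.49 and the calcium pump gene Atp2a1 by 2.42 ± 0.41. Myog, a transcription factor of myoblast differentiation, went from 10.72 ± 0.31 to 12.98 ± 0.90 (SD, n = 2). Chrna1, Tcap and Rapsn differed by 0.27, 0.20 and -0.04. MACS means of 15 of the 25 genes lay below the array median, and the list's median was 1.95 with the floor and 2.35 with no filter. Genes below the array median in both MACS cultures were again tested only if above it in both PP6 cultures. Tnnt1 differed by 1.97 with the floor. As with the leukocyte list, PP6 replicate 3 lay further from MACS, at 3.77, than PP6 replicate 2, at 2.29.

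Genes of satellite cells and myoblasts, the resident muscle precursors and their progeny, did not pass as a list. The median of 13 tested members was -0.19, camera gave an adjusted p of 0.597, and 0 members passed when adjusted over the list alone. Without MACS replicate 2 the list passed as lower, with a median of -0.44 and an adjusted p of 0.0455. The median was -0.36 without PP6 replicate 2, -0.07 without MACS replicate 3, 0.01 without PP6 replicate 3, -0.02 with no filter and -0.31 with median centring. Pax7, a transcription factor of satellite cells, had a log2 signal of 11.74 ± 0.50 in MACS and 10.18 ± 0.56 in PP6, and a p of 0.0585 adjusted over the list alone. With no filter another probe set stood for Pax7, with -0.50. Myod1 stood at 12.82 ± 0.14 and 12.63 ± 0.42, a difference that ran from -0.48 without PP6 replicate 2 to 0.11 without PP6 replicate 3. Des, the intermediate filament gene of muscle cells, differed by 1.27 ± 0.28 (SE) with a p of 0.058 adjusted over the list alone, and its other probe set gave -0.28. Itga7 differed by 0.65 ± 0.35, or 0.38 without PP6 replicate 2 and 0.41 without MACS replicate 2. Fgfr4 differed by -0.78 ± 0.42, or -1.29 without PP6 replicate 2 and -0.28 without PP6 replicate 3, and its probe sets differed in sign.

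Fibroblast matrix genes rose as a list in PP6, with a median of 1.00 log2 units and a camera adjusted p of 1.73e-08. The adjusted p was 0.411 with an estimated correlation. Adjusted over the list alone 11 of 29 members rose and 0 fell, and over all genes 0 passed. Collagen gene Col1a1 rose by 2.17 ± 0.35 (SE), the gelatinase gene Mmp2 by 1.23 ± 0.19, Timp2 by 1.08 ± 0.20 and fibronectin gene Fn1 by 1.06 ± 0.20. Probe sets of Timp2 ranged from 0.08 to 1.96. Without MACS replicate 2 the list's median was 0.36. Insulin-like growth factor, Wnt and TGF-beta genes passed as higher at an adjusted p of 0.00198, but not with an estimated correlation, where the adjusted p was 0.411, with a median of 0.24 and a mean of 0.58. Adjusted over the list alone 4 of 19 rose: Igfbp4 by 1.90 ± 0.24, Tgfbi by 1.65 ± 0.23, Igfbp7 by 1.44 ± 0.20 and Igfbp5 by 1.26 ± 0.26. Probe sets ranged from 1.15 to 2.32 for Igfbp4, 0.92 to 1.65 for Tgfbi and 0.47 to 1.26 for Igfbp5. Without MACS replicate 2 that list missed the threshold at an adjusted p of 0.066, and its median was 0.77 without PP6 replicate 2, 0.37 without PP6 replicate 3, 0.47 without MACS replicate 3, 0.11 with median centring and 0.42 with no filter.

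Adipogenic genes passed as higher at an adjusted p of 0.00298, but not with an estimated correlation, where the adjusted p was 0.411. Their median was 0.47 over 12 genes, or 0.27 without MACS replicate 3. The estimated correlation of -0.011 lay under the preset 0.01. Every other list that passed had an estimate above it, such as 0.514 for matrix and 0.239 for contractile genes. The unadjusted camera p of the list still went from 0.00132 to 0.0774, on 2 degrees of freedom. Lpl and the desaturase gene Scd1, at 1.87 ± 0.42 (SE), were the 2 members that rose when adjusted over the list alone, while Dgat2 differed by 0.98 ± 0.28 and Cd36 by 0.98 ± 0.32. A further probe set gave 0.20 for Scd1 and 0.32 for Dgat2, and Cd36 stood at 0.60 without PP6 replicate 3. Tendon, cartilage and bone genes went both ways, with a median of 0.37 over 8 genes and an adjusted p of 0.653. That median was 0.08 without PP6 replicate 3, 0.15 without MACS replicate 3, 0.18 with the floor at the array median, 0.25 with median centring and -0.07 with no filter. The small proteoglycan gene Fmod rose by 3.37 ± 0.46 when adjusted over the list alone, and all 6 of its tested probe sets lay between 2.77 and 3.52. Bmp4 differed by -1.71 ± 0.61, the tendon factor Scx by -0.69 ± 0.26 and Alpl by 0.89 ± 0.46. Bmp4 stood at -1.02 without MACS replicate 2 and -0.97 with the floor, and Scx at 1.53 with no filter.

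Endothelial genes passed as lower in PP6 at an adjusted p of 0.00121, but not with an estimated correlation, where the adjusted p was 0.411, with a median of -0.35 and 12 of 15 members negative. No member passed when adjusted over the list alone: Vwf differed by -1.04 ± 0.26 (SE), Sox17 by -1.09 ± 0.27, Erg by -1.33 ± 0.44 and Tek by -0.59 ± 0.26. A further Sox17 probe set gave -0.49, and Erg stood at -0.71 without MACS replicate 2 and -0.73 with no filter. Smooth muscle and pericyte genes passed as higher at an adjusted p of 0.0043, but not with an estimated correlation, where the adjusted p was 0.411, with a median of 0.66 over 8 genes and 0 past the threshold when adjusted over the list alone. Abcc9 differed by 1.31 ± 0.40, Notch3 by 0.93 ± 0.36, Tpm2 by 0.64 ± 0.25 and Acta2 by 0.42 ± 0.21. Abcc9 stood at 0.81 and Tpm2 at 0.40 without PP6 replicate 2, and Notch3 at 0.52 and Acta2 at 0.25 without MACS replicate 2. Probe sets ranged from 0.56 to 1.31 for Abcc9 and 0.50 to 2.25 for Tpm2. The call was lost without PP6 replicate 2, at a median of 0.37. It was also lost without probe sets that can match several transcripts, at a median of 0.60 and an adjusted p of 0.0554. Schwann and neural genes passed as higher at an adjusted p of 0.00989, but not with an estimated correlation, where the adjusted p was 0.411, with a median of 0.67, or 0.36 without MACS replicate 2. The filter at the 75th percentile ended that call, with an adjusted p of 0.235. The glial cadherin gene Cdh19 rose by 2.85 ± 0.62 when adjusted over the list alone, while Erbb3 differed by 1.54 ± 0.47, Mbp by 0.77 ± 0.38 and Ncam1 by -0.84 ± 0.27. With the floor Cdh19 differed by 1.75, and another probe set stood for Mbp, with 1.26. Probe sets ranged from 0.77 to 2.65 for Mbp and from -0.84 to -0.15 for Ncam1.

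Surface genes of mesenchymal progenitors did not pass as a list, with an adjusted p of 0.969. Their median of 0.04 and mean of 0.07 were above 0 while camera placed them below other genes, and the median was -0.08 with median centring. It was 0.18 without MACS replicate 3, 0.14 without PP6 replicate 2, -0.12 without MACS replicate 2 and -0.06 without PP6 replicate 3. Thy1 differed by 1.01 ± 0.32 (SE), Itga5 by -1.29 ± 0.42, Eng by -0.59 ± 0.21 and Cd34 by -0.76 ± 0.31. The other probe set of Itga5 gave 0.97, and Cd34 stood at -0.37 without MACS replicate 2 and -1.16 without MACS replicate 3. Pdgfra differed by 0.03 ± 0.22, with probe sets from -0.69 to 0.24, and ran from -0.12 without MACS replicate 2 to 0.18 without MACS replicate 3. Stem cell associated genes gave an adjusted p of 0.597, a median of -0.27 and a mean of 0.08. Sox2 differed by 2.10 ± 0.66, Prom1 by 1.65 ± 0.54, Kit by 0.54 ± 0.32, Myc by -0.65 ± 0.29 and Bmi1 by -0.51 ± 0.26. Sox2 stood at 1.11 with the floor and Myc at -0.39 without MACS replicate 2. Imprinted genes gave an adjusted p of 0.94 and a median of 0.10, which turned to -0.02 with median centring. That median was 0.33 without PP6 replicate 3, 0.04 without PP6 replicate 2 and 0.41 with no filter. Igf2 differed by 1.05 ± 0.28, its receptor gene Igf2r by -0.92 ± 0.25, Ndn by 0.56 ± 0.23 and Plagl1 by -1.08 ± 0.36, and probe sets of Plagl1 and Ndn differed in sign. The other probe set of Igf2r gave -0.11, and Ndn stood at 0.36 without MACS replicate 2. None of these members passed when adjusted over its list alone.

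Cell cycle genes passed as lower in PP6 at an adjusted p of 0.000101, but not with an estimated correlation, where the adjusted p was 0.419. Of 26 tested members 25 were negative, with a median of -0.39, and 0 passed when adjusted over the list alone. Mcm4 differed by -1.18 ± 0.27 (SE), Mcm6 by -0.80 ± 0.24 and Mcm7 by -0.75 ± 0.19. Top2a differed by -1.17 ± 0.27, with another probe set at 0.50, and probe sets of Mcm7 ranged from -0.89 to -0.05. The median was -0.65 without MACS replicate 2, -0.17 without MACS replicate 3 and -0.25 without PP6 replicate 3. Immediate early genes, the first to respond to growth factors and stress, passed as lower at an adjusted p of 0.0013, but not with an estimated correlation, where the adjusted p was 0.411, with a median of -0.34. It was -0.56 without MACS replicate 2 and -0.55 without PP6 replicate 2. Ccn1 was the only 1 of 20 members that fell when adjusted over the list alone, and Egr1 differed by -1.19 ± 0.28, Klf6 by -1.05 ± 0.29 and Hspa1b by -0.71 ± 0.20.

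Chemokine and inflammatory genes moved both ways, with a median of 0.35 and an adjusted p of 0.423. Adjusted over the list alone 4 of 15 rose and 3 fell. Saa3, Cxcl12, Cxcl14, at 1.46 ± 0.22 (SE), and Lcn2 rose, and Cxcl1, Cxcl5 and Ptgs2 fell. The list passed as higher without MACS replicate 3, at an adjusted p of 0.0361, and its median was -0.33 without MACS replicate 2, 0.15 with no filter and 0.22 with median centring. Interferon response genes passed as lower at an adjusted p of 0.0205, but not with an estimated correlation, where the adjusted p was 0.666, with a median of -0.34 and 0 of 17 past the threshold when adjusted over the list alone. Rsad2 differed by -1.27 ± 0.46, Ifit1 by -0.62 ± 0.27, Igtp by -0.56 ± 0.25 and Oas1a by -0.47 ± 0.28. Rsad2 stood at -1.97 and Oas1a at -0.74 without MACS replicate 2, and at -0.58 and -0.19 without MACS replicate 3. Without PP6 replicate 2 Ifit1 stood at -0.38 and Oas1a at -0.29. This call was lost without MACS replicate 3, at a median of -0.07 and an adjusted p of 0.724, without PP6 replicate 2, at -0.19 and 0.413, and with the filter at the 75th percentile, at 0.121. Without MACS replicate 2 the interferon median was -0.65. Hypoxia and glycolysis genes passed as higher at an adjusted p of 0.0109, but not with an estimated correlation, where the adjusted p was 0.411, with a median of 0.27 and 0 of 18 past the threshold when adjusted over the list alone. Ankrd37 differed by 0.99 ± 0.21, Ldha by 0.55 ± 0.23, Pgk1 by 0.54 ± 0.23 and Bnip3 by 0.67 ± 0.30. Bnip3 stood at 0.30 without MACS replicate 2 and 1.03 without MACS replicate 3, and a further probe set of Pgk1 gave 0.30. With quantile normalization Ldha stood at 0.09 and Pgk1 at 0.06. The list's call was lost without MACS replicate 2, at a median of 0.11 and an adjusted p of 0.0723, without PP6 replicate 2, at 0.21 and 0.174, with quantile normalization, at 0.0522, and with the mean over probe sets, at 0.0603. The median was 0.49 without MACS replicate 3 and 0.14 with median centring.

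**Figure D2:**
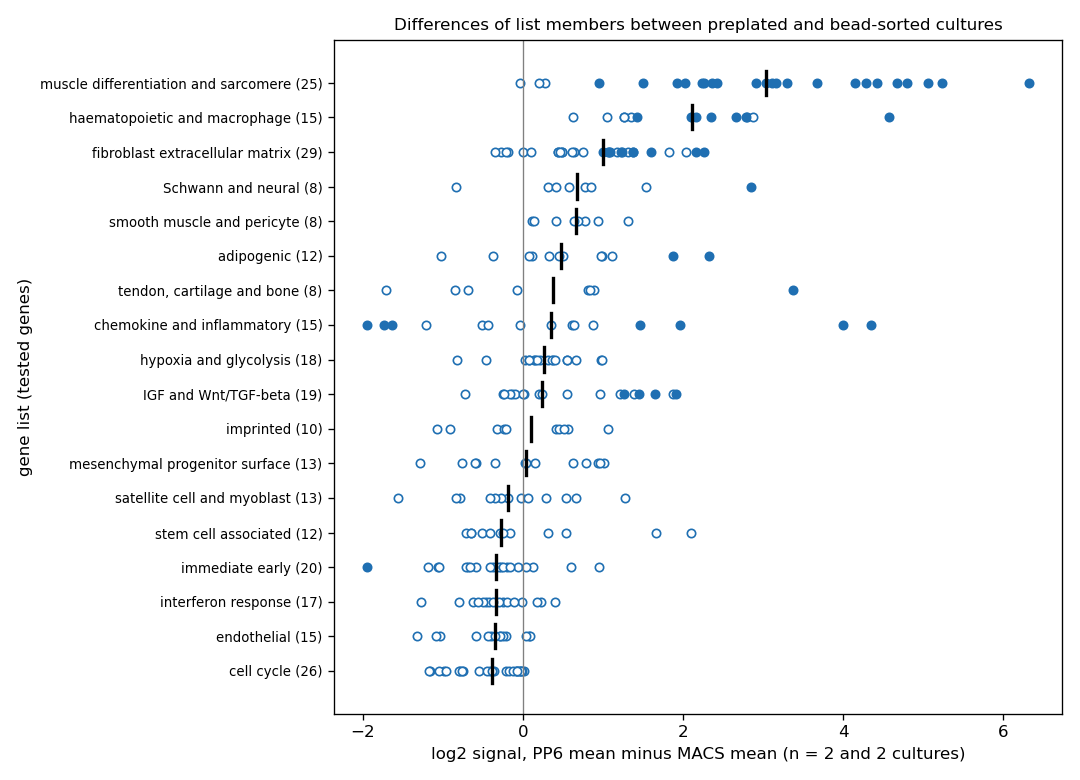
Difference in mean log2 signal between PP6 and MACS (horizontal axis, n = 2 cultures each) for tested members of 18 gene lists (vertical axis, number of tested genes in brackets). Each circle is a gene, filled where its p adjusted over the list alone was under 0.05, and black bars are list medians, from -0.39 for cell cycle to 3.03 for muscle differentiation and sarcomere.

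Of the erythroid list only Klf1 was tested, with a difference of -0.16 ± 0.93 (SE) that ran from -1.03 without PP6 replicate 2 to 0.70 without PP6 replicate 3. Of the sex chromosome list only Xist was tested, with -1.75 ± 0.75 and a spread of 0.11 in MACS and 1.72 in PP6 (SD, n = 2). It stood at -2.96 without PP6 replicate 2 and -0.54 without PP6 replicate 3. Fry passed no list as moving on balance in 1 direction, with a smallest adjusted p of 0.192. With 2 residual degrees of freedom this does not show that no list moved. The contractile list, at a median of 3.03, had an unadjusted fry p of 0.0174. The fry test for change in either direction gave an adjusted p under 0.05 for 12 of 18 lists, the smallest 0.00449 for the chemokine list. Of these 12 lists, 6 had not passed camera: satellite cell (0.0161), mesenchymal (0.0217), tendon (0.0161), stem cell (0.0337), imprinted (0.0148) and chemokine genes. Of the lists that had passed camera, 6 stayed above 0.05: haematopoietic (0.0796), matrix (0.0597), smooth muscle (0.157), Schwann (0.0629), cell cycle (0.0796) and interferon genes (0.412).

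Technical error and RNA quality were read from the arrays themselves. The 100 probe sets placed on both array types gave differences between PP6 and MACS that correlated at r = 0.769 across probe sets (Spearman's rho 0.742), and the SD of the disagreement was 0.24 log2 units. The ratio of 3' to 5' signal of the Gapdh control on MOE430A was 12.1 and 5.34 in MACS and 6.65 and 10.3 in PP6, so the groups overlapped. For beta-actin it was 4.95 and 3.38 in MACS and 4.24 and 4.83 in PP6. On MOE430B the Gapdh ratios were 14.3 and 6.29 in MACS and 8.59 and 10.1 in PP6, and the beta-actin ratios 5.67 and 2.85 in MACS and 3.90 and 5.28 in PP6. Signal was thus higher at the 3' end on every array, with 2.85 as the lowest ratio, so overlap of the groups does not show intact RNA. MACS replicate 2 had the highest ratio of both controls on both array types. Without that culture the matrix list's median was 0.36 rather than 1.00. Whether RNA quality played a part was not tested. Control probe sets for bacterial polyadenylated transcripts were brighter in PP6. Their geometric mean signal on MOE430A was 45940 and 33090 in MACS and 64490 and 111100 in PP6. Whether this bears on the higher leukocyte and contractile genes was not tested.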

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

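Dim signals limit the folds, since no measure of background came with the values used here. Of the alternatives, only the floor at the array median was chosen after the data were seen. When a culture is left out, the lone culture of its group is assumed to vary like the other group. Calls past the threshold numbered 0 in each direction as reported. Fitted alone, the array types gave 55 probe sets (41 genes) higher and 16 (8) lower. The filter at the 75th percentile gave 5 and 5 higher, the floor 18 (13) higher and 5 (1) lower, and leaving out a culture 0 to 1 higher for both counts. At an unadjusted p under 0.05, 2216 probe sets were higher with no filter and 739 with the stricter filter. Leaving out a culture gave 648 to 1790 higher and 918 to 1348 lower. The other alternatives, apart from the replicate block, gave 0 calls.

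The labels do not say whether the replicate numbers pair cultures. The difference between replicates 2 and 3 in MACS correlated with that in PP6 at -0.033 across probe sets. The data thus showed no shift shared by replicate number, which does not exclude shared animals. A replicate block gave 2 probe sets and 2 genes higher, Ngp and Chil3, and changed no list call, though it turned the direction of the mesenchymal list (adjusted p 0.88).

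Of 12 lists that passed, 7 (contractile, haematopoietic, matrix, adipogenic, endothelial, cell cycle and immediate early) did so in all 16 alternatives at the preset correlation. With an estimated correlation none passed: cell cycle stood at 0.419, interferon at 0.666 and the other 10 at 0.411. That camera test has only 2 degrees of freedom, so these misses do not decide whether the calls hold. Estimated correlations of the 12 lists ran from -0.011 for adipogenic to 0.704 for haematopoietic genes, with 0.514 for matrix and 0.323 for cell cycle genes. Calls at the preset 0.01 therefore rest partly on that setting. Lost calls, as adjusted p, were smooth muscle without _x_at and _s_at probe sets (0.0554), Schwann (0.235) and interferon (0.121) at the 75th percentile, and hypoxia with quantile normalization (0.0522) and the mean over probe sets (0.0603). With a culture left out, the adjusted p ranged from 0.000584 to 0.0743 for smooth muscle, 0.000114 to 0.724 for interferon, 0.00348 to 0.174 for hypoxia and 0.000163 to 0.066 for the growth factor list. It ranged from 0.0455 to 0.973 for satellite cell, 0.562 to 0.855 for mesenchymal, 0.315 to 0.936 for tendon, 0.694 to 0.976 for imprinted and 0.0361 to 0.852 for chemokine genes. These 5 had not passed as reported and turned direction in some of these runs. The satellite list also turned with the mean over probe sets (0.956), the imprinted list at the 75th percentile (0.915), and the mesenchymal list with quantile normalization (0.801), median centring (0.972), the 75th percentile (0.937) and no trend (0.976). The tendon list had too few genes at the 75th percentile. The causes were not tested.

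Some single genes turned direction. With no filter a dimmer MOE430A probe set stood for Med14 (1.41), Bdkrb2 (0.39) and Scx (1.53). Plagl1 gave 1.125 without _x_at and _s_at probe sets. The mean over probe sets gave 0.27 for Fgfr4, 0.022 for Plagl1, 0.092 for Myod1 and -0.14 for Pdgfra. Median centring gave -0.098 for Pdgfra and the floor 0.12 for Klf1. Without a culture Klf1 ranged from -1.03 to 0.70, Myod1 from -0.48 to 0.11 and Pdgfra from -0.12 to 0.18.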

Other observations

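The tests on granulocyte, lymphoid, satellite cell, newly formed muscle, Y-linked and whole-array signal were chosen after the results were seen, while the matched random lists were planned before theirs was known. The 5 further lists described here were written after the main results were seen.

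P-selectin gene Selp, an adhesion molecule gene of endothelial cells and platelets that was picked after its values were seen, was lower in PP6 on all 3 of its probe sets, by -2.54 log2 units each. A granulocyte list, which left out the 10 genes named as higher in PP6, had a median difference of 1.76 over 11 measured genes, and 9 of them were higher in both PP6 cultures than in both MACS cultures. The cathelicidin gene Camp differed by 5.02, the cathepsin G gene Ctsg by 4.80 and the lactoferrin gene Ltf by 3.92. Medians were -0.23 for 6 B cell genes, 0.68 for 6 T cell genes including Thy1, which stromal cells also express, and 0.53 for 7 mast cell genes. The B cell median was -0.12 in PP6 replicate 2 and -0.41 in PP6 replicate 3. Mature fast fibre genes had a median of 1.09 over 10 genes, from -0.59 for Ampd1 to 4.80 for Myh1.

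The haematopoietic and macrophage list was higher in PP6 at the preset correlation of camera, but did not pass with an estimated one (adjusted p 0.411), and 8 of its 15 members passed when adjusted over the list alone. Of 10000 random lists matched on mean signal, 0 reached the haematopoietic median of 2.11. This argues against a shift of all probe sets of like signal. It does not test labelling that acts on particular transcripts, and both PP6 cultures had less concentrated RNA than both MACS cultures. Lymphoid cells were not excluded: the median was -0.154 over 11 B and T cell genes other than Thy1, but only 3 of these passed the filter, and genes near background cannot exclude a source. Myeloid cells among the preplated cells stay an open candidate source, which the granulocyte median of 1.76 does not decide: 4 of the 11 genes (Camp, Ctsg, Ltf and Elane) had already passed on MOE430A alone, the other 7 had a median of 0.97, 0 of the 11 stood in another list and 2 lay above the array median in both MACS cultures. Ngp and S100a8 reached log2 signals of 16.17 and 15.56 in PP6, the bead sort against CD45 would remove such cells from MACS, and the preparation itself, with its different yield and culture, stays open and untested.

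The contractile list was higher in PP6 at the preset correlation of camera, but did not pass with an estimated one (adjusted p 0.411). Over all genes 0 of its 25 members passed, and 5 passed with MOE430A fitted alone. No matched random list of 10000 reached the list's median of 3.03, that is 0. This argues against a shift of all probe sets of like signal, but does not test labelling that acts on particular transcripts. A larger share of myogenic cells in an unchanged state would raise satellite cell and myoblast genes about as much as contractile genes. The satellite cell and myoblast median of -0.187, with an SD of 0.73 between members, argues against this for the list as a whole. With a culture left out that median ran from -0.44 to 0.01. With no filter the medians of the 2 lists were -0.02 and 2.35. Of 13 satellite cell and myoblast members 5 were higher, Des by 1.27, and 8 lower. The list was not checked for genes that other cells express, so the argument is limited. Fragments of adult fibres stay open. Genes of newly formed muscle (Myog, Mymk, Myh3, Actc1, Tnnt2 and Myl4) were higher by a median of 2.969, from 2.26 to 6.32. All 6 belong to the contractile list, were picked after their values were seen and had passed within it, while Chrna1 stood at 0.27. Mature fast fibre genes had a lower median of 1.09, with an SD of 1.63 between members. Their differences, from -0.59 to 4.80, overlapped those of newly formed muscle, so the comparison does not decide. The preparation itself stays open and untested, and the labels name muscle cells as the contaminating type in both preparations.

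Xist, the transcript that silences an X chromosome in female cells, was lower in PP6 replicate 3 than in the other 3 cultures, with differences from their mean between -3.86 and -2.79 log2 units on 3 probe sets. A dimmer array is argued against, since 9293 probe sets of similar signal had a median difference of -0.012. Male cells in that culture may be the source, as 5 of 9 probe sets for Eif2s3y, Kdm5d and Uty were highest there, with a mean log2 signal of 8.24 against 6.67 to 7.46 elsewhere. These 9 probe sets were all below the filter, so the evidence is thin, and the labels used here give no sex.

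The 4 cultures can be divided into 2 and 2 in 3 ways. The division into MACS and PP6 gave 2760 probe sets at an unadjusted p under 0.05, and the highest of the others gave 865. So few divisions are too few for a share under 0.05.

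Bacterial polyadenylated control signal on MOE430B was 142800, 206400, 262200 and 413600 in the cultures whose labelled RNA concentrations were 65, 55, 35 and 15 ng/ul. On MOE430A it was 33090, 45940, 64490 and 111100 in that order. Hybridisation controls in that order stood at 7582, 13570, 13610 and 21180 on MOE430A and at 35230, 66980, 49960 and 79100 on MOE430B.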
